A study of Mus musculus with 12 samples.

How the data were processed

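Fecal 16S rRNA gene amplicons were measured in mice. The labels describe 12 groups, given by 2 sexes, 2 prior feeds (CD or HfiD, each fed for 5 weeks) and 3 durations of subsequent HFD feeding (0, 4 and 8 weeks). The series title identifies HfiD with high fiber intake and HFD with high fat feeding; the labels do not spell out CD, and the code is kept here. Per the labels' protocols, DNA was extracted from frozen fecal pellets with a magnetic kit for soil and stool, the V4 region was amplified with barcoded primers, and a PCR-free library was sequenced on an Illumina instrument. The submitters' processing notes name fastp 0.23.1 and R 4.0.3 without saying what each was used for. The denoising or clustering step, the reference database, the classifier, any rarefaction and the way libraries were combined into a group value are not given in the sources used here.

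The values used were relative abundances per phylum, deposited by the authors as fractions of the 16S reads of a group, in 1 table for males and 1 for females. They were multiplied by 100 and are given as percent of reads. There were 84 named phyla for males and 34 for females, each with a further row named Others. Columns summed to between 99.9998% and 100.0006%. Per the files, values have 6 decimals of a fraction, a step of 0.0001%, so a phylum listed at 0 can lie below that step. Read depth was unknown, so no counting interval or detection limit could be set, and no count of reads was inferred from the fractions.

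Each group column is the authors' own value for a group and stands as 1 value with no SD and no n. A further 115 library columns in 2 tables (67 male and 48 female) carry codes that match no single sample label, so they were not assigned to groups, which was done by name only, and were not used. The tests planned before the data were examined (exact permutation tests, limma as the alternative, PERMANOVA, residual permutation of the interaction, leaving out libraries) all need libraries assigned to groups, and none was run here; with a key from codes to groups they would apply. All comparisons below are therefore differences between single group values, with no replicate check and no p-value, and the spread between animals behind them is unknown.

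The male columns name the feeds, with HfiD shortened to fiD in those of 4 and 8 weeks. The female columns are coded C and T with a suffix for 4 or 8 weeks. C was read as CD, the only feed label with that letter, and T as HfiD by elimination. The labels do not state this code, so the direction of each difference between feeds in females rests on that reading. The sexes come from separate tables. Where levels of both sexes are given side by side, the difference between the sexes was not tested.

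Phyla were compared on log2(percent + 0.01). A phylum entered a count if its mean over the columns compared was at least 0.01%, and it was counted as apart if the log2 values differed by at least 2-fold. That size rule was set after the data were examined, because the planned tests were not run. Folds in the text are plain ratios of percentages and are given only where both values are at least 0.01%. Phyla were named by a rule fixed beforehand, a list of 10 mouse gut phyla in every comparison; phyla outside the list were named where they reached 0.1% in 1 column and were at least 2-fold apart, the size again replacing the planned adjusted p. A list of 12 phyla typical of soil or water, also fixed beforehand, was summed per column. Whether reads of these phyla came from sources other than the gut was not tested. Older and newer phylum names were matched through a written list of synonyms. Summary measures were the ratio of Firmicutes to Bacteroidota, the Bray-Curtis dissimilarity over all rows and the Shannon index (natural log) over named phyla. The change of the difference between feeds with HFD was the difference at 4 or 8 weeks minus that at 0 weeks.

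Alternatives were pseudocounts of 0.001% and 0.1%, no filter, a filter at 0.1%, ratios with no pseudocount, and a centred log ratio. Further ones were rescaling without the Others row, inverse Simpson for Shannon, Aitchison for Bray-Curtis, and shares in percent for log ratios. The ratios with no pseudocount stood in for the planned scale with no log. They were still compared as log2, so they check the pseudocount only. The comparison code was also run on simulated data of 80 phyla, with no noise, no pseudocount, no filter and no rescaling of the changed shares. It returned the 10 made 8-fold higher and the 10 made 8-fold lower, which checks the arithmetic only. The pseudocount and filter used here were not exercised by it. Calculations used Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, with matplotlib 3.10.9 for the plots.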

Results

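Phylum profiles of feces were available as 1 group value for each combination of sex, prior feed (CD or the high fiber feed HfiD, 5 weeks) and duration of the following high fat feed (HFD, 0, 4 or 8 weeks). The design asked how the gut communities of the 2 feed groups moved over the 3 time points. Firmicutes and Bacteroidota, the phyla that hold most anaerobic gut fermenters, together made up 67.2% to 86.7% of reads in males and 78.8% to 88.5% in females. The 10 listed gut phyla covered 96.8% to 98.5% of reads in males and 98.5% to 99.9997% in females. There were no replicates within a group in the values used, so none of the differences below has an error or a test, and read depth was unknown. In females, CD and HfiD stand for the columns coded C and T, the second by elimination only.

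**Figure D1:**
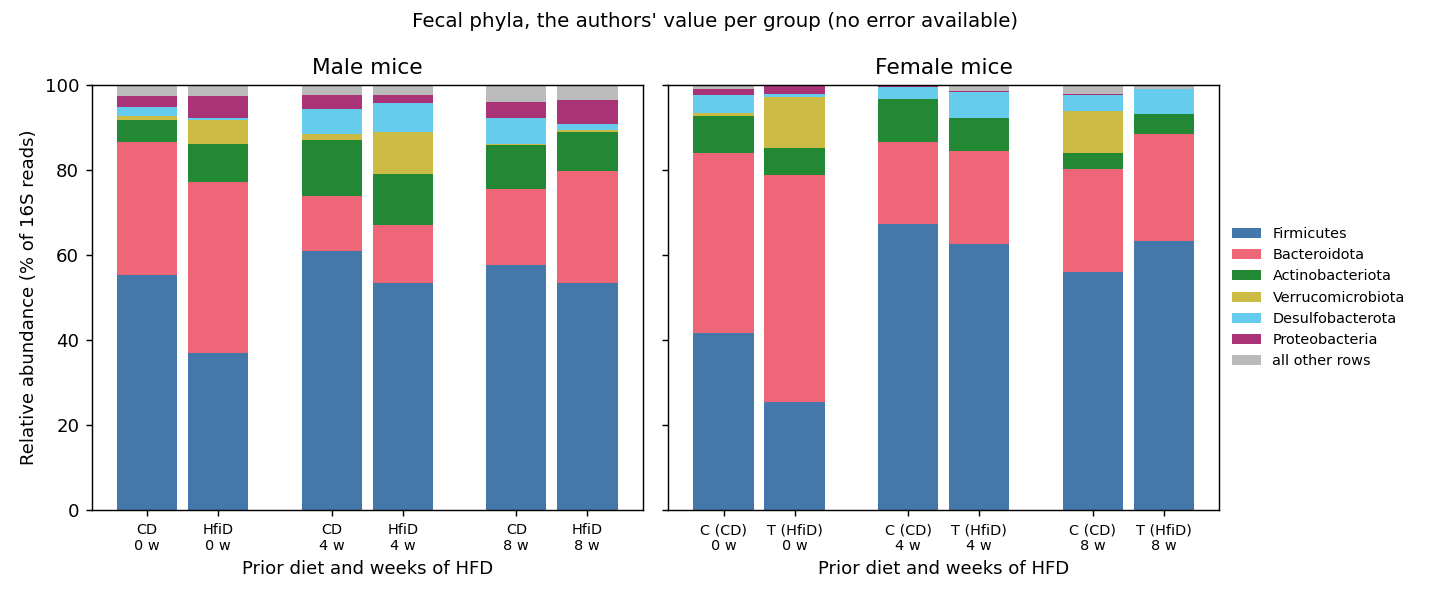
Relative abundance (percent of 16S reads, vertical axis) of the 6 most abundant phyla and of all other rows together, stacked per group, with prior feed and weeks of HFD along the horizontal axis. Each bar is the authors' single value per group, with no error. Bacteroidota take up less of each bar at 4 and 8 weeks of HFD than in the same feed group at 0 weeks.

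Before HFD, the HfiD columns held less Firmicutes and Desulfobacterota and more Bacteroidota and Verrucomicrobiota than the CD columns in both sexes. In males, Firmicutes, which include the Clostridia and lactobacilli, stood at 36.9% after HfiD and 55.3% after CD. Bacteroidota, which include degraders of plant and host glycans, stood at 40.4% after HfiD and 31.4% after CD. Verrucomicrobiota, the phylum of the mucin degrader Akkermansia, stood at 5.47% against 0.917%, 5.96-fold higher after HfiD. Desulfobacterota, which hold sulfate reducers such as Desulfovibrio, stood at 0.562% against 2.24%, 3.99-fold lower after HfiD. In females, Firmicutes were 25.4% after HfiD and 41.7% after CD, and Bacteroidota were 53.3% and 42.3%. Female Verrucomicrobiota were 11.8% after HfiD and 0.842% after CD, 14.1-fold higher, and Desulfobacterota were 0.697% and 4.26%, 6.11-fold lower. The ratio of Firmicutes to Bacteroidota was 0.914 after HfiD and 1.76 after CD in males, and 0.477 and 0.985 in females, a log2 difference of -0.94 and -1.05.

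Among the remaining gut phyla at 0 weeks, Actinobacteriota differed in opposite directions in the sexes, and Proteobacteria, Deferribacterota, Patescibacteria and Cyanobacteria in the same direction. Actinobacteriota, the phylum of Bifidobacterium, were 1.81-fold higher after HfiD in males (8.96% against 4.96%) and 1.34-fold lower in females (6.44% against 8.62%), and the female direction turned under a centred log ratio. Proteobacteria, the phylum of Escherichia, were 1.94-fold higher after HfiD in males (5.07% against 2.62%) and 1.56-fold higher in females (1.99% against 1.27%). Deferribacterota, the phylum of the mucus dweller Mucispirillum, were 1.51-fold lower after HfiD in males and 4.98-fold lower in females, at or below 0.165% in the 4 columns; the female log2 difference was -0.99, short of 2-fold, with a pseudocount of 0.1%. Patescibacteria, small-celled bacteria that often live on other bacteria, stood at 0.0538% after HfiD and 0.0621% after CD in males, and at 0.0112% and 0.143% in females. Cyanobacteria, a class of reads that can include chloroplasts from feed, stood at 0.676% against 0.604% in males, a direction that turned under a centred log ratio, and at 0.114% against 0.0572% in females. The female differences in Proteobacteria and Cyanobacteria exceeded 2-fold under a centred log ratio (1.21 and 1.45). Campylobacterota, the phylum of Helicobacter, stood at 0.044% against 0.026% in males and at no more than 0.0003% in any female column. Of the 10 gut phyla, all past the abundance filter in males, 1 was at least 2-fold higher and 1 at least 2-fold lower after HfiD. In females 9 passed the filter, 1 at least 2-fold higher and 3 at least 2-fold lower. Outside the list, Caldatribacteriota were 4.14-fold higher after HfiD in males (0.202% against 0.0488%), and Acidobacteriota were 3.53-fold lower in females (0.0326% against 0.115%). The Acidobacteriota difference was short of 2-fold under a centred log ratio and with a pseudocount of 0.1%.

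After 4 weeks of HFD, the percentages of Firmicutes and Bacteroidota differed less between the feed groups than at 0 weeks. For female Firmicutes the order of the times turned under a centred log ratio, with log2 differences of -0.92 at 4 weeks and -0.15 at 0 weeks. Male Firmicutes were 53.4% after HfiD and 61.0% after CD, and Bacteroidota were 13.7% and 13.0%. Female Firmicutes were 62.6% and 67.3%, and Bacteroidota were 21.8% and 19.2%, a direction that turned under a centred log ratio. Male Verrucomicrobiota were 9.80% after HfiD and 1.36% after CD, 7.20-fold higher. In females they were listed at 0 after HfiD and at 0.0008% after CD. Desulfobacterota stood at 6.81% after HfiD against 6.03% after CD in males, and at 6.22% against 2.82% in females, 2.20-fold higher, but short of 2-fold under a centred log ratio (log2 difference of 0.32). Female Deferribacterota were 1.37% after HfiD and 0.0384% after CD, 35.7-fold higher, while male values were 0.247% and 0.351%. Proteobacteria were 1.60-fold lower after HfiD in males (2.03% against 3.25%) and 3.34-fold higher in females (0.226% against 0.0676%), the latter short of 2-fold under a centred log ratio (0.79) and with a pseudocount of 0.1% (0.96). Actinobacteriota stood at 11.9% against 13.1% in males and at 7.72% against 10.3% in females, the latter above 2-fold under a centred log ratio (-1.23). Patescibacteria were 1.20-fold lower after HfiD in males and 3.22-fold lower in females (a log2 difference of -0.84 with a pseudocount of 0.1%). Cyanobacteria stood at 0.241% against 0.187% in males and at 0.0023% against 0.001% in females. Male Campylobacterota were 0.279% against 0.214%, and both female columns listed them at 0.

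After 8 weeks of HFD, male Verrucomicrobiota and Desulfobacterota differed in the same directions as at 0 weeks, and the female values differed in the opposite directions. Male Verrucomicrobiota were 0.643% after HfiD and 0.252% after CD, 2.55-fold higher. In females they were listed at 0 after HfiD and stood at 9.93% after CD. Male Desulfobacterota were 1.44% after HfiD and 6.22% after CD, 4.31-fold lower, and female values were 5.80% and 3.83%, 1.51-fold higher. Male Deferribacterota were 5.64-fold lower after HfiD (0.0488% against 0.275%), and female Deferribacterota were 1.61-fold higher (0.324% against 0.201%). Bacteroidota stood at 26.3% after HfiD and 18.1% after CD in males, and at 25.1% and 24.2% in females. Firmicutes stood at 53.5% and 57.6% in males, and at 63.4% and 56.0% in females. Proteobacteria were 1.49-fold higher after HfiD in males (5.47% against 3.67%), and stood at 0.0872% against 0.0974% in females, a direction that turned under a centred log ratio. Female Patescibacteria were 5.97-fold lower after HfiD (0.0865% against 0.517%), short of 2-fold under a centred log ratio (-0.70), and male values were 0.377% and 0.252%. Actinobacteriota stood at 9.03% against 10.2% in males and at 4.70% against 3.69% in females. Cyanobacteria stood at 0.349% against 0.307% in males and at 0.0211% against 0.0153% in females. Under a centred log ratio the female differences at 8 weeks were above 2-fold for Firmicutes (a log2 difference of 1.93), Bacteroidota (1.81), Actinobacteriota (2.10), Proteobacteria (1.61), Desulfobacterota (2.35), Deferribacterota (2.42) and Cyanobacteria (2.05). Centring subtracted the same mean from every phylum there, a log2 difference of -1.75, where the median was 0.12. Verrucomicrobiota (-9.96) and Euryarchaeota (-7.11) had the largest log2 differences behind that mean. Both were listed at 0 after HfiD, so their sizes, and with them the shift, depend on the pseudocount. Male Campylobacterota were 0.0141% against 0.0134%, and both female columns listed them at 0. Outside the list, Acidobacteriota were 2.96-fold higher after HfiD in males (0.565% against 0.191%). Euryarchaeota, archaea that include gut methanogens, stood at 1.38% in the female CD column and were listed at 0 after HfiD.

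**Figure D2:**
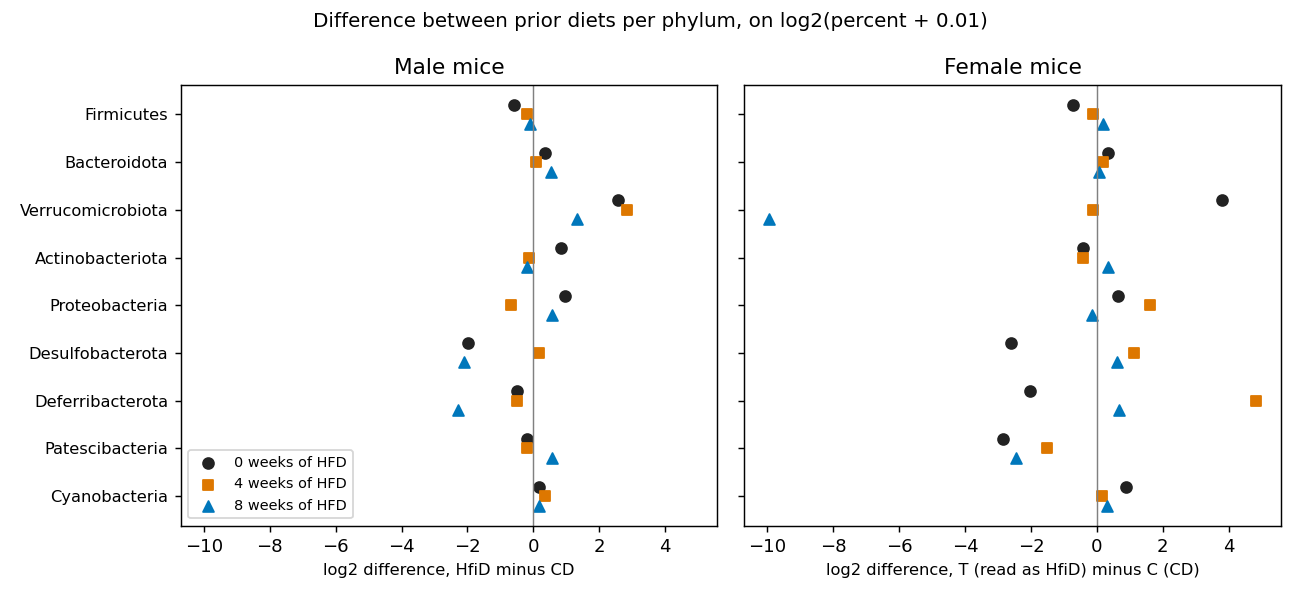
Difference between the prior feeds (horizontal axis, log2(percent + 0.01), HfiD minus CD) for 9 gut phyla (vertical axis) at 0, 4 and 8 weeks of HFD, in males and in females, 1 value per point with no error. In males, Verrucomicrobiota lie between 1.32 and 2.84 at the 3 times; in females they lie at 3.80 at 0 weeks and at -9.96 at 8 weeks, where the HfiD column is listed at 0, so that the size depends on the pseudocount.

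Counted over all named phyla past the filter, 3 of 28 in males were at least 2-fold higher and 1 lower after HfiD at 0 weeks (3 and 2 under a centred log ratio). At 4 weeks 1 of 27 was higher and 2 lower, and at 8 weeks 4 of 35 were higher and 3 lower (5 and 3 under a centred log ratio). With a pseudocount of 0.1% the male numbers were 2 and 1, 1 and 0, and 2 and 2 at 0, 4 and 8 weeks. A filter at 0.1% gave the same male numbers. In females 1 of 12 was higher and 6 lower at 0 weeks (3 and 3 under a centred log ratio), 3 of 7 were higher and 1 lower at 4 weeks (1 and 2), and 0 of 10 were higher and 3 lower at 8 weeks (7 and 2). With a pseudocount of 0.1% the female numbers were 1 and 2, 2 and 0, and 0 and 3 at 0, 4 and 8 weeks. With a filter at 0.1% they were 1 and 1, 3 and 1, and 0 and 3. Of the phyla listed as typical of soil or water, 12 had a row in males and 10 in females. They summed to 0.936% to 1.68% of reads in the male columns and to 0 to 0.251% in the female columns. In females at 0 weeks, this sum was 0.0807% after HfiD and 0.251% after CD, and 3 of the 6 phyla counted as lower after HfiD belong to it. In males at 8 weeks, 3 of the 4 phyla counted as higher after HfiD belong to it, with sums of 1.68% after HfiD and 1.55% after CD.

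The Bray-Curtis dissimilarity between the feed groups was 0.204 at 0 weeks, 0.103 at 4 weeks and 0.112 at 8 weeks in males. In females it was 0.228, 0.0751 and 0.118. Under the Aitchison distance, in which scarce phyla weigh as much as abundant ones, 8 weeks was the most distant time in both sexes (5.05 in males and 11.2 in females). That distance sums over phyla past the filter, in time order 28, 27 and 35 in males and 12, 7 and 10 in females. It can therefore be larger where more phyla passed. In females at 8 weeks, Verrucomicrobiota and Euryarchaeota were listed at 0 after HfiD, so their part in it depends on the pseudocount. The Shannon index at 0 weeks was 1.44 after HfiD and 1.21 after CD in males, and 1.24 and 1.22 in females, where the sign of the difference turned under inverse Simpson. At 4 weeks it was 1.49 and 1.31 in males, and 1.07 and 0.938 in females. At 8 weeks it was 1.34 and 1.37 in males, a sign that also turned under inverse Simpson, and 0.978 and 1.25 in females. The ratio of Firmicutes to Bacteroidota at 4 weeks was 3.89 after HfiD and 4.70 after CD in males, and 2.87 and 3.50 in females. At 8 weeks it was 2.04 and 3.19 in males, and 2.52 and 2.32 in females, the 1 comparison of the 6 in which it was higher after HfiD (log2 difference of 0.12).

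At 4 and 8 weeks of HFD, Firmicutes were higher and Bacteroidota lower than at 0 weeks in 8 of 8 comparisons, over both sexes, both prior feeds and both times. No group was kept off HFD at 4 or 8 weeks, so HFD cannot be told apart from age or time of collection. HFD also followed the prior feed, so its start cannot be told apart from the end of CD or HfiD. The same limits hold for all comparisons over time and for changes of the difference between feeds. Each column of 0 weeks served for both later times, and shares within a column are tied together, so the 8 comparisons are not independent. A centred log ratio turned the direction of Firmicutes in the male CD group at both times, and that of Bacteroidota in the female CD group at 4 weeks and the female HfiD group at 8 weeks. The ratio of the 2 phyla, which centring leaves unchanged, was higher than at 0 weeks in 8 of 8. In males after CD it was 2.67-fold higher at 4 weeks and 1.81-fold at 8 weeks, and after HfiD 4.25-fold and 2.23-fold. In females after CD it was 3.55-fold higher at 4 weeks and 2.35-fold at 8 weeks, and after HfiD 6.01-fold and 5.29-fold. Bacteroidota in the male HfiD group stood at 40.4%, 13.7% and 26.3% at 0, 4 and 8 weeks, and in the female HfiD group at 53.3%, 21.8% and 25.1%, where the log2 difference at 4 weeks was -0.35 under a centred log ratio. Under a centred log ratio, Firmicutes in the female CD group at 4 weeks were above 2-fold higher (2.70), and Bacteroidota in the male CD group at 8 weeks above 2-fold lower (-1.34). Firmicutes in the female HfiD group stood at 25.4%, 62.6% and 63.4%.

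Desulfobacterota were higher than at 0 weeks in 6 of 8 comparisons. After HfiD they were 12.1-fold higher at 4 weeks and 2.57-fold at 8 weeks in males, and 8.93-fold and 8.33-fold higher in females. After CD they were 2.69-fold and 2.77-fold higher in males, the value at 8 weeks short of 2-fold under a centred log ratio (0.92), and 1.51-fold and 1.11-fold lower in females, where the direction at 4 weeks turned under a centred log ratio. Verrucomicrobiota in males stood at 5.47%, 9.80% and 0.643% at 0, 4 and 8 weeks after HfiD, and at 0.917%, 1.36% and 0.252% after CD. In females they stood at 11.8% at 0 weeks and were listed at 0 at 4 and 8 weeks after HfiD, and stood at 0.842%, 0.0008% and 9.93% after CD. Female Proteobacteria were lower than at 0 weeks at both times, by 18.8-fold and 13.1-fold after CD and by 8.82-fold and 22.8-fold after HfiD. Male Proteobacteria stood at 2.62%, 3.25% and 3.67% after CD and at 5.07%, 2.03% and 5.47% after HfiD, and the directions at 8 weeks turned under a centred log ratio. Actinobacteriota after CD were 2.64-fold and 2.06-fold higher in males, the value at 8 weeks short of 2-fold under a centred log ratio (0.50), and 1.19-fold higher and 2.34-fold lower in females, at 4 and 8 weeks. After HfiD they were 1.33-fold and 1.01-fold higher in males, and 1.20-fold higher and 1.37-fold lower in females, and both directions at 8 weeks turned under a centred log ratio. The female values at 4 weeks were above 2-fold on that scale, at 2.26 after CD and 1.20 after HfiD.

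Among the scarcer gut phyla, Cyanobacteria were lower than at 0 weeks in 8 of 8 comparisons, by 3.23-fold and 1.97-fold in males after CD and by 2.81-fold and 1.94-fold after HfiD. Under a centred log ratio the male values at 8 weeks exceeded 2-fold (-1.50 and -1.14), and female values fell short of it after CD at 4 weeks (-0.61) and after HfiD at 8 weeks (-0.88). With a pseudocount of 0.1% the female values were also short of 2-fold after CD at 4 and 8 weeks (-0.64 and -0.45) and after HfiD at 8 weeks (-0.82). Female Deferribacterota after HfiD were 41.4-fold higher at 4 weeks and 9.79-fold at 8 weeks. After CD they were 4.29-fold lower at 4 weeks and 1.22-fold higher at 8 weeks. The direction after CD at 4 weeks turned under a centred log ratio, and its size was short of 2-fold with a pseudocount of 0.1% (-0.94). Male Deferribacterota after CD were 4.75-fold and 3.72-fold higher, and after HfiD stood at 0.0491%, 0.247% and 0.0488%. Patescibacteria at 4 weeks were lower than at 0 weeks in males, by 1.57-fold after CD and 1.63-fold after HfiD, and higher in females, by 1.26-fold (a log2 difference of 2.32 under a centred log ratio) and 4.99-fold (0.49 with a pseudocount of 0.1%). At 8 weeks they were higher than at 0 weeks in the 4 groups, by 4.06-fold and 7.00-fold in males and 3.62-fold and 7.72-fold in females, after CD and HfiD; the last was short of 2-fold with a pseudocount of 0.1% (0.75). Male Campylobacterota were 8.23-fold higher at 4 weeks after CD and 6.33-fold after HfiD, and at 8 weeks stood 1.94-fold and 3.12-fold lower than at 0 weeks, the latter short of 2-fold with a pseudocount of 0.1% (-0.34) and the former above it under a centred log ratio (-1.17).

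Outside the gut list, male Gemmatimonadota were lower at 4 weeks than at 0 weeks, by 4.24-fold after CD and 3.15-fold after HfiD. The latter was short of 2-fold with a pseudocount of 0.1%. Male Caldatribacteriota after HfiD stood at 0.202% at 0 weeks, were listed at 0 at 4 weeks and stood at 0.1444% at 8 weeks. After CD they stood at 0.0488%, 0.0005% and 0.1625%, 3.33-fold higher at 8 weeks than at 0 weeks. That difference after CD at 8 weeks was short of 2-fold with a pseudocount of 0.1%. In the male CD group at 8 weeks, Chloroflexi were 2.62-fold and Nitrospirota 2.16-fold higher, and Gemmatimonadota 2.70-fold and Acidobacteriota 2.38-fold lower. Chloroflexi and Nitrospirota in that group were short of 2-fold under a centred log ratio. Nitrospirota, Gemmatimonadota and Acidobacteriota were short of it with a pseudocount of 0.1%. Marinimicrobia stood at 0.151% there and were listed at 0 at 0 weeks. Female Acidobacteriota after CD stood at 0.115% at 0 weeks, 0.0003% at 4 weeks and 0.0008% at 8 weeks. Female Euryarchaeota after CD were listed at 0 at 0 weeks and stood at 1.38% at 8 weeks. The sum of soil or water phyla in females was 0.251% at 0 weeks, 0.0018% at 4 weeks and 0.0103% at 8 weeks after CD, and 0.0807%, 0 and 0.0021% after HfiD. In males it was 1.34%, 0.936% and 1.55% after CD, and 1.18%, 1.07% and 1.68% after HfiD. All named phyla past the filter were also counted over time, with numbers under a centred log ratio in brackets where they differ. In males after CD, 10 of 30 were at least 2-fold higher and 5 lower at 4 weeks (10 and 8). At 8 weeks 13 of 33 were higher and 5 lower (9 and 10). After HfiD the male numbers were 6 and 9 of 29 at 4 weeks. At 8 weeks they were 6 and 3 of 30 (4 and 4). The female numbers after CD were 0 and 8 of 12 at 4 weeks (4 and 3). At 8 weeks they were 3 and 6 of 13. After HfiD they were 4 and 6 of 11 at both times (5 and 4 at 4 weeks, 4 and 2 at 8 weeks). With a filter at 0.1% the male numbers were 4 and 3, then 7 and 3, after CD. After HfiD they were 3 and 4, then 2 and 1. A pseudocount of 0.1% gave 6 and 1 after CD at 8 weeks and otherwise the same male numbers. With a filter at 0.1% the female numbers were 0 and 4, then 3 and 2, after CD, and 3 and 3 at both times after HfiD. With a pseudocount of 0.1% they were 0 and 4, then 3 and 3, after CD, and 3 and 4, then 3 and 3, after HfiD.

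The difference between the feed groups itself was set against that at 0 weeks. The log2 difference in the ratio of Firmicutes to Bacteroidota, HfiD minus CD, was higher by 0.67 at 4 weeks and 0.30 at 8 weeks in males, and by 0.76 and 1.17 in females. In percentage points, the difference in Firmicutes was higher by 10.8 and 14.3 in males and by 11.6 and 23.6 in females. The difference in Bacteroidota lay -8.16 and -0.717 points from that at 0 weeks in males, the value at 8 weeks being positive on the log2 scale (0.18), and -8.44 and -10.1 points in females. For Verrucomicrobiota the gap to 0 weeks was 3.89 and -4.16 points in males and -11.0 and -20.9 points in females. For Desulfobacterota it was 2.45 and -3.10 points in males (2.15 and -0.12 on the log2 scale, 3.99-fold and 4.31-fold lower after HfiD at 0 and 8 weeks) and 6.96 and 5.53 points in females (3.73 and 3.19). For Actinobacteriota it was -5.16 and -5.17 points in males and -0.380 and 3.20 points in females, the female value at 4 weeks being 0.0074 on the log2 scale. None of these gaps was tested.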

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

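The comparisons and the test here were chosen after the data were examined, and none of the differences was tested, because each rests on 1 value per group. They were singled out because the difference between prior feeds, HfiD minus CD on log2(percent + 0.01), was at least 1.5-fold in opposite directions in 2 sexes or at 2 times, for gut phyla of at least 0.1% in 1 of the columns.

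Verrucomicrobiota went from a difference of 3.80 in females at 0 weeks to -9.96 at 8 weeks, 13.75 apart, and the male difference at 8 weeks was 1.32, which lies 11.27 above the female one. Because the female HfiD column is listed at 0 at 8 weeks, these sizes depend on the pseudocount, while the directions do not. An exchange of the female columns of 8 weeks was set against the directions of the gut phyla: apart from Verrucomicrobiota, left out because it prompted the test, 4 of 6 that reached 0.1% at 8 weeks kept the direction they had at 4 weeks, and 3 of 6 under a centred log ratio. With 1 value per group these numbers decide nothing, and an exchange stays open. A few animals with high Verrucomicrobiota in the CD group and a loss of the phylum in the HfiD group also stay open, since the libraries behind the columns were not analysed here.

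In this paragraph, gaps between times are the value at 0 weeks minus that at the later time, so a negative gap marks a higher value later, and gaps between sexes are males minus females. Desulfobacterota differed by -2.59 in females at 0 weeks, by 1.14 at 4 weeks (0.32 under a centred log ratio; a gap of -3.73) and by 0.60 at 8 weeks (2.35 under a centred log ratio; a gap of -3.19). At 8 weeks the male difference was -2.10, a gap of -2.70 to the female one. Deferribacterota differed by -2.02 in females at 0 weeks (-0.99 with a pseudocount of 0.1%), by 4.83 at 4 weeks (a gap of -6.85) and by 0.66 at 8 weeks (2.42 under a centred log ratio; a gap of -2.68), and the male difference of -2.28 at 8 weeks (-1.33 with a pseudocount of 0.1%) left a gap of -2.94 to the female one. Proteobacteria differed by 0.95 in males at 0 weeks and by -0.68 at 4 weeks (a gap of 1.63), and the female difference of 1.60 at 4 weeks (0.79 under a centred log ratio, 0.96 with a pseudocount of 0.1%) left a gap of -2.28 between the sexes.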

How the results depend on the processing

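The alternatives were planned before the data were examined. The rules for judging them were set afterwards, since no spread was available: a value counted as moved if it differed by over 1.5 times, a distance if its rank among the 3 times differed, and measures in another unit were compared by sign only. In place of the planned scale with no log, counts and gut phylum differences were run as ratios with no pseudocount. These were still compared as log2, so they are no check on the log scale. Leaving out libraries, limma, adjustment over all 6 feed comparisons and every permutation test were not run, since the library columns were not assigned to groups. No paired analysis was possible because the columns used carry no replicate numbers and the library columns were not assigned to groups. The sign of the Firmicutes to Bacteroidota differences was kept in all 18 comparisons when the Firmicutes share in percent was used. Counts of phyla at least 2-fold apart depended on scarce phyla. For the prior feeds, a pseudocount of 0.001% gave 9 in males at 0 weeks (4 in the chosen setting) and 13 at 8 weeks (7), as did ratios with no pseudocount (9 and 13). A pseudocount of 0.1% gave 1 and 4 in males at 4 and 8 weeks, and 3 and 2 in females at 0 and 4 weeks. A filter at 0.1% gave 1, 4 and, in females at 0 weeks, 2. A centred log ratio gave 9 in females at 8 weeks (3). For weeks of HFD, a pseudocount of 0.1% gave 7, 7, 7 and 3 in the male comparisons (15, 18, 15 and 9), 4 in females after CD at 4 weeks (8) and 6 after HfiD at 8 weeks (10). A filter at 0.1% gave 7, 10, 7 and 3 in males, and 4, 5, 6 and 6 in females. No filter gave 14 in males after HfiD at 8 weeks, and a centred log ratio gave 6 in females after HfiD at 8 weeks. Aitchison distances were 4.73 and 5.05 in males and 6.05 and 11.2 in females at 0 and 8 weeks, and the order of the 2 times turned. In males they sum over 28 and 35 phyla, so the turn there was not separated from the number of phyla. In females the value at 8 weeks includes Verrucomicrobiota and Euryarchaeota, listed at 0 after HfiD, and so depends on the pseudocount. Inverse Simpson turned the diversity difference to 0.103 in males at 8 weeks and to -0.0218 in females at 0 weeks. The centred log ratio removed the mean log2 difference of the phyla past the filter, which ranged from -2.00 (females after CD, 4 against 0 weeks) to 0.82 (females, HfiD against CD at 4 weeks), and turned 14 of 131 directions of gut phyla and moved a further 47 in size. A pseudocount of 0.1% turned none and moved 35 of 131, that of 0.001% moved 3, and ratios with no pseudocount moved 6 of 128. Of 63 gut phylum differences of at least 2-fold, 11 fell short of it under a centred log ratio and 10 with a pseudocount of 0.1%, and 19 others reached it under a centred log ratio only. Between feeds the directions that turned were Cyanobacteria in males at 0 weeks (-0.0627), and in females Actinobacteriota at 0 weeks (0.15), Bacteroidota at 4 weeks (-0.63) and Proteobacteria at 8 weeks (1.61). Over time in males they were Firmicutes after CD at 4 and 8 weeks (-0.13 and -0.48), Proteobacteria after CD and HfiD at 8 weeks (-0.0585 and -0.0922) and Actinobacteriota after HfiD at 8 weeks (-0.19). In females they were Bacteroidota, Desulfobacterota and Deferribacterota after CD at 4 weeks (0.87, 1.41 and 0.15), and Bacteroidota and Actinobacteriota after HfiD at 8 weeks (0.0222 and 0.66). In percent instead of log2, 9 of 38 changes of the feed difference turned, for phyla that reached 0.1% in a column of that sex, a limit set after the data were examined. In males these were Deferribacterota, Campylobacterota, Patescibacteria and Cyanobacteria at 4 weeks (-0.0798, 0.0465, 0.0018 and -0.0183), and Bacteroidota and Cyanobacteria at 8 weeks (-0.717 and -0.0306). In females they were Actinobacteriota and Proteobacteria at 4 weeks (-0.380 and -0.560) and Patescibacteria at 8 weeks (-0.2985). Centring weighs each phylum alike, so a few can set the mean it removes. Between feeds in females it was -1.75 at 8 weeks (median 0.12), with Verrucomicrobiota at -9.96 and Euryarchaeota at -7.11. At 4 weeks it was 0.82 (median 0.18), with Deferribacterota at 4.83. Where directions turned over time in females it lay near the median: -2.00 and -2.10 (CD, 4 weeks), -1.11 and -1.09 (HfiD, 8 weeks). Causes were not tested. Rescaling without the Others row moved none of the 20 summary values it applies to and 1 of 131 gut phylum differences.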

Other observations

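The phyla and tests in this part were chosen after the data were examined. The female CD column at 8 weeks listed 6 phyla that were at 0 in the other 5 female columns: Euryarchaeota at 1.38%, and Fusobacteriota, Spirochaetota, Fibrobacterota, Halobacterota and Synergistota at 0.0031% or less. The female CD column at 0 weeks listed 4 such phyla, none above 0.0036%. In males, Euryarchaeota reached 0.0727% after CD and 0.0088% after HfiD at 4 weeks, and did not exceed 0.0015% in the other 4 male columns.

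Both male columns of 8 weeks listed 11 phyla outside the gut list that were at 0 in the other 4 male columns, together 0.222% of reads after CD and 0.108% after HfiD. Marinimicrobia, a lineage known from seawater, made up most of this, at 0.151% and 0.0793%. The male columns of 0 weeks and of 4 weeks each shared 1 such phylum, and no pair of columns from different weeks shared more than 1. Of the 11, AncK6, Aerophobota, Aquificota and Altiarchaeota stood at 0.0007% or less, near the step of 0.0001%. The male columns of 8 weeks also listed the most named phyla above 0, 71 after CD and 69 after HfiD. The other male columns listed 50 to 57. Read depth was unknown, so the number of shared phyla was not separated from it. A library or sequencing batch shared by the male libraries of 8 weeks is a candidate source, but time and batch coincide, so the 11 phyla cannot tell it from an effect of 8 weeks of HFD as such. Of the 11 phyla, 0 were above 0 in a female column of 8 weeks; this does not settle it either, because the female table used here has no row for any of the 11, and its Others row held 0.113% and 0.515% of reads in those columns. The named phyla above 0 numbered 50 to 71 per male column and 8 to 26 per female column; this difference was not tested, and depth and table construction may differ between the sexes.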
